A study of Mus musculus with 6 samples.

How the data were processed

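RNA of mouse KH2 ESCs (C57BL/6 x 129 background) was enriched for polyA transcripts and sequenced as single-end reads of 50 bases, per the labels. The 6 libraries were 1 per group: KH2 untreated, KH2 with PD0325901 for 48 hours, and the iErk1; Erk KO line with Dox, without Dox for 48 hours, without Dox for 96 hours, and without Dox for 96 hours with PD0325901 during the last 48. The inhibitor's dose and the use of feeder cells were not given in the labels.

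Per the file headers, the authors counted uniquely mapped reads per gene, and this read count sums to the library total in each file. The deposited RPKM values were computed by the authors as reads per kilobase of gene length and 1e6 reads of that total, which was checked on every gene. The third deposited value is the percent of the gene's length covered by reads, by the authors. The genome build was mm9 per the submitters' processing notes, and the aligner and the annotation were not given in the sources used here. Genes without reads have no row in a file and were set to 0. The files were joined by NCBI gene ID over 18857 genes, 4 of the files lacked gene symbols, and symbols for 18805 genes came from the RefSeq annotation by gene ID. That annotation is of a later build than mm9, so no coordinates were used from it. Gene lengths differed between files for 41 genes. Unique-read counting makes genes of families with similar copies uncertain, and the files do not separate strands.

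The depth per library was 9.09, 9.05, 9.41, 9.70, 9.96 and 9.83 times 1e6 reads, in the order above. The 10 genes with the most reads took between 4.64% and 6.12% of a library. A floor of 3 reads stands for the limit that a count of 0 allows. Intervals are exact 95% Clopper-Pearson intervals of the share of a gene's reads in either library, scaled by the totals. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

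The comparisons, tests, gene lists, alternatives and rules that follow were chosen before the data were examined, except where stated. Each of 5 comparisons set 1 library against another: PD0325901 in KH2 cells, PD0325901 in Erk KO cells, Dox withdrawal for 48 hours, Dox withdrawal for 96 hours, and the Dox-maintained line against KH2. The design text names 3 of these, and the last 2 were added as implied by the groups. A gene passed the size rule with a log2 ratio of RPKM plus 0.5 of at least 1 in size, an RPKM of at least 1 in the higher library, at least 20 reads over both libraries and a 95% interval that excluded 1. No p-value was computed for these comparisons.

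An effect of PD0325901 common to both cell states was tested on the 4 libraries of the 2 treated and untreated pairs with edgeR's quasi-likelihood F test, with cell state as a block, TMM scaling and at least 20 reads over the 4 libraries. The fit had 1 residual degree of freedom, a median of 13.8 prior degrees of freedom and a common dispersion of 0.0076. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Standard errors were computed from the log2 fold change and the F value. The difference between the pairs was planned as a description with a limit of 4-fold. An edgeR test of it over all 6 libraries was added after the data were seen. It treats the 48 and 96 hour libraries without Dox as 1 state, which leaves 1 residual degree of freedom, so its spread includes the difference between those time points.

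There were 33 gene lists, described by the number of members passing in each direction, the median log2 ratio, and the medians of 10000 random lists matched on mean expression in 20 bins. Genes were named by a rule. For each comparison it took the 8 highest and 8 lowest log2 ratios among genes that passed with at least 100 reads over the 2 libraries and had a proper name, up to 3 passing members of each list, and a fixed set of Erk pathway, pluripotency and cell cycle genes. For the common test it took the 10 highest and 10 lowest fold changes past the threshold and list members. Some genes that the rule names are not reported here. Members named to complete a count of at most 10 were chosen after their values were seen. Agreement between comparisons was described across genes by Pearson r, Spearman rho and shared genes, and for comparisons with a common library beside 100 Poisson simulations of groups without a difference.

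The size rule and the common test were tested on simulated data with planted changes. In the common test 45 of 48 genes planted at 0.25-fold and 26 of 50 at 0.5-fold were called. At 2-fold 35 of 50 and at 4-fold 48 of 50 were called, with 7 of 14447 genes without a change. These data had a dispersion of 0.02 for every gene and the same planted change in both pairs. The counts therefore do not give a rate of false calls in the real data. The added test of the difference, on data simulated with a dispersion of 0.02 and the 2 pooled libraries alike, called 68 of 100 genes planted at 0.25-fold, 75 of 100 at 4-fold and 16 of 14764 without a difference. The size rule passed 38 of 38, 32 of 33, 34 of 36, 30 of 30 and 32 of 32 genes planted at 0.25-fold in the 5 comparisons in the order above. At 4-fold it passed 39 of 39, 36 of 37, 40 of 40, 41 of 41 and 37 of 39. Of genes without a change it passed 13 of 12517, 8 of 11679, 5 of 11096, 9 of 11471 and 7 of 11955. At 2-fold, the limit of the rule, it passed 11 of 41, 5 of 30, 15 of 40, 8 of 33 and 11 of 41. Reads for the size rule were simulated with counting error only. These counts therefore leave out variation between cultures and do not give a rate of false passes in the data.

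Alternatives for the comparisons were pseudocounts of 0.1 and 1, no filter on low values, an RPKM of at least 3, TMM scaling, DESeq2 size factors, a 3-fold limit and no counting interval. For the common test they were DESeq2, no scaling beyond library totals, no filter on low counts, no block, and all 6 libraries with 3 or 4 untreated states. List medians were also taken over members with an RPKM of at least 1. A GC-corrected log2 ratio, a count without the fibroblast and cytoskeleton lists and the test of the difference between the pairs were chosen after seeing the data. Leaving out a library removes a whole group, or for the common test the last residual degree of freedom, so no such alternative was run. The computations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.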

Results

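PolyA RNA was sequenced in 6 libraries of mouse KH2 embryonic stem cells (ESCs), with 1 library per group. Wild-type cells were untreated or treated for 48 hours with PD0325901, an inhibitor of the kinase Mek, which activates the Erk kinases. The other 4 libraries came from cells labelled iErk1; Erk KO, in which Erk1 is switched on by doxycycline (Dox). They were cultured with Dox, without Dox for 48 hours, without Dox for 96 hours, or without Dox for 96 hours with PD0325901. Library totals, in reads assigned to genes times 1e6, ran from 9.05 to 9.96, and between 16042 and 17403 genes had at least 1 read. In the untreated KH2 library 1 read on a transcript of 2 kb equalled 0.055 RPKM (reads per kilobase of gene length and 1e6 library reads). With 1 library per group there was no replicate check, so the ratios below compare libraries rather than conditions, and their 95% intervals cover counting error only. Log2 ratios were computed on RPKM plus 0.5, and folds on reads scaled to the library totals.

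The Dox-inducible gene was expressed at lower levels in all 4 libraries of the engineered line than in KH2 cells. Mapk3 (gene ID 26417), which encodes Erk1, had 56.4 and 52.8 RPKM in the KH2 libraries and 14.8 RPKM in the engineered line with Dox. It was 2.15-fold lower after 48 hours without Dox (interval 1.72 to 2.70), at 6.86 RPKM, and stood at 6.75 RPKM after 96 hours. The treated 96 hour library had 9.18 RPKM. After 96 hours without Dox the Mapk3 level was 0.120 of that in KH2 cells (0.098 to 0.145). Reads still covered 89.7% of the Mapk3 transcript in that library. The files hold gene totals, so they do not show which exons the remaining reads covered.

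**Figure D1:**
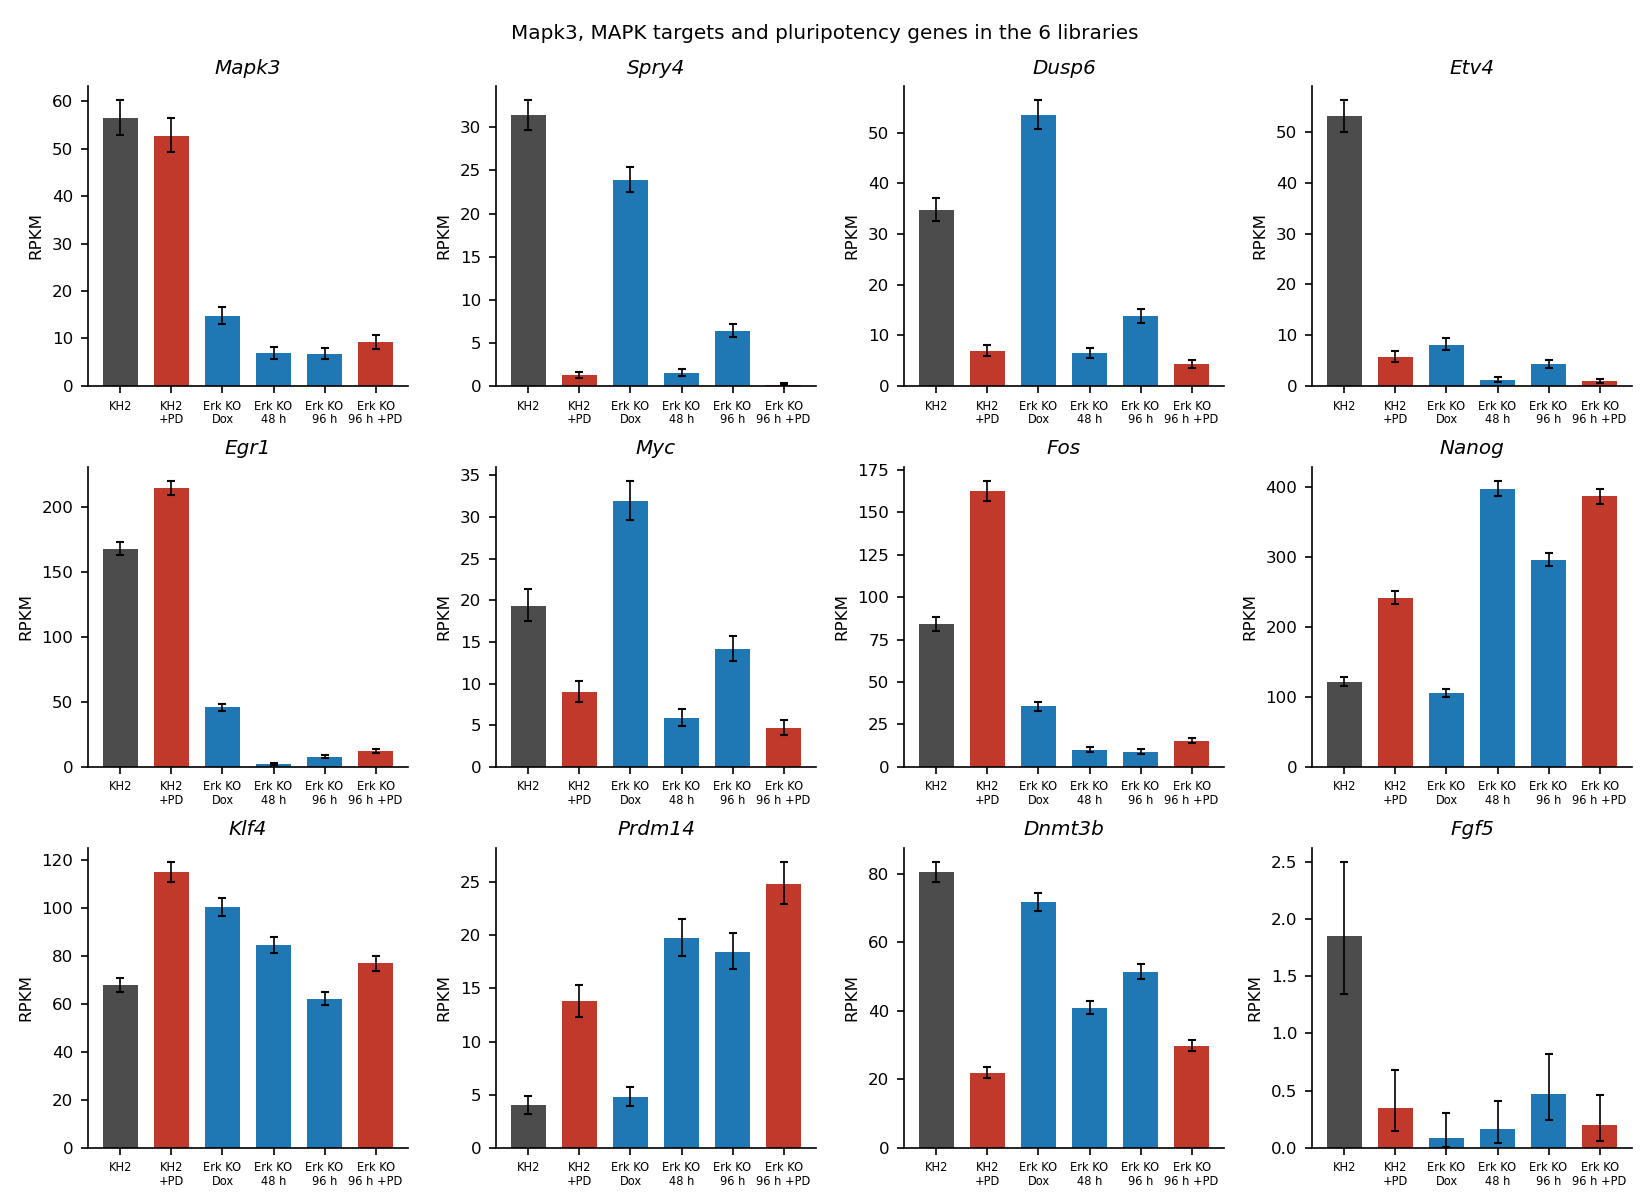
RPKM of 12 genes in the 6 libraries, with 1 bar per library and exact 95% Poisson counting intervals as error bars (grey, untreated KH2; red, PD0325901; blue, engineered line without inhibitor). Mapk3 was at 56.4 RPKM in untreated KH2 cells and at 6.86 RPKM in the engineered line after 48 hours without Dox, and Spry4 was at 31.4 RPKM and 1.22 RPKM in untreated and treated KH2 cells.

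The first comparison named in the design asked what Mek inhibition did in wild-type ESCs. Of 30 MAPK feedback and immediate target genes, 6 were lower in the treated library, among them Spry4, an inhibitor of receptor tyrosine kinase signalling, at 25.7-fold lower (19.4 to 34.7), the transcription factor gene Etv4, 9.28-fold lower (7.69 to 11.3), and the Erk phosphatase gene Dusp6 (log2 ratio −2.24), at 34.8 RPKM untreated and 6.95 RPKM treated. Of 18 naive pluripotency genes 3 passed as higher, Spic (log2 ratio 2.14), Prdm14 (1.67) and Tbx3 (1.19). Of 20 genes of formative or primed pluripotency 10 were lower, and these included the DNA methyltransferase genes Dnmt3b, which went from 80.5 to 22.0 RPKM, and Dnmt3a (log2 ratio −1.58). Of 26 fibroblast markers 18 were higher, with Col1a1 at 96.4 RPKM untreated and 878 RPKM treated. Of 12787 genes tested, 493 were higher and 156 lower by the size rule, which is 5.08%.

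The 6 lower MAPK targets were Spry4, Etv4, Dusp6, Etv1, Myc and Spred1, while 3 were higher (Ier3, Epha4 and Rasgef1a) and 21 did not pass. The list's median log2 ratio was −0.34, and the middle 95% of matched random lists lay between −0.16 and 0.10. Myc was 2.15-fold lower (1.81 to 2.57). The immediate early genes Egr1 (0.35) and Fos (0.95) had positive log2 ratios below the 2-fold limit, and Spry2 (−0.97) and Etv5 (−0.53) had negative ones. Of the naive genes 0 were lower and 15 did not pass, with a median of 0.63 against −0.20 to 0.09 for random lists. Nanog, a core factor of naive cells, was at 122 RPKM untreated and 242 RPKM treated, 1.98-fold higher (1.86 to 2.11), just short of the limit. Klf4 (0.76), Klf2 (0.57) and Esrrb (0.27) were also below it, and Zfp42 was at −0.09. Of 18 general pluripotency genes only Utf1 passed, at 2.74-fold lower (2.55 to 2.95). The list's median was −0.56, and Pou5f1 (−0.51) and Sox2 (0.03) did not pass. In the formative and primed list 10 of 20 genes were lower and 0 higher, with a median of −1.14 against −0.18 to 0.18. The list included Tcf15 (4.43-fold lower), Lef1 (3.15-fold lower) and Fgf5, which had 43 reads untreated and 8 reads treated. The list of DNA methylation machinery held Dnmt3b and Dnmt3a as its 2 lower genes and Prdm14 as its 1 higher gene. Dnmt3l (−0.68) did not pass.

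Among the genes with the highest ratios in treated KH2 cells, Prelp, a collagen-binding proteoglycan, was 30.7-fold higher (24.2 to 39.6), Ccn5 was 23.6-fold higher, Ccdc80 20.4-fold higher, the collagen-fibril gene Fmod 14.2-fold higher, Ly6a 12.5-fold higher and Saa3 10.7-fold higher. Ogn had 253 reads against 1 and Aspn 108 reads against 1. In the fixed list of fibroblast markers, 18 of 26 genes were higher and 0 lower, with a median of 1.70 against −0.17 to 0.09. Col1a1 was 9.11-fold higher, and Ptx3 (3.07) and Timp3 (2.98) were near that. In the list of cytoskeleton, adhesion and matrix genes, 14 of 30 were higher and 0 lower, with a median of 0.93. Acta2, the smooth muscle actin gene, was 6.48-fold higher, and Myl9 (2.21) and Acta1 (2.16) also passed. The genes with the lowest ratios besides Spry4 and Etv4 were Serpinb2 (14.0-fold lower), Tgm3 (13.8-fold lower), Gbx2 (7.11-fold lower), the hormone precursor gene Trh (5.65-fold lower), Enpp3 (5.58-fold lower) and Dusp6. Ly6a belongs to a gene family whose shared sequence makes counts of uniquely mapped reads uncertain.

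Of 8 CDK inhibitor genes 2 were higher in treated KH2 cells. Cdkn1a, which encodes p21, was 2.81-fold higher, at 72.3 RPKM untreated and 203 RPKM treated, and Cdkn2b had a log2 ratio of 1.21. In the list of p53 targets, Cdkn1a, Gdf15 (1.17) and Fas were higher, Plk3 (−1.37) was lower and 26 did not pass. No gene of the lists for G1/S and DNA replication (34 genes), G2/M (29), DNA damage response and repair (38), telomere maintenance (26), apoptosis (24), ribosomal proteins (42), cholesterol synthesis (24), Polycomb and Trithorax (23), BMP and Nodal targets (17), 2-cell-like state (18), the MAPK cascade (23) or the Y chromosome (8) passed. Only 4 of the 18 2-cell-like and 4 of the 8 Y-linked genes reached the limits on reads and RPKM, so the others could not pass. The repair list had a median of −0.22 against −0.14 to 0.09. Ccnd1 (−0.42), Tert (−0.04), Map2k1 (0.28) and Map2k2 (0.09), which encode cyclin D1, telomerase reverse transcriptase and the Mek kinases, were within 2-fold. Wnt targets had 3 lower genes of 18 (Lef1, Cdx2 and Myc). In the remaining lists few genes passed. Sparc (1.65), Col4a2 (1.36) and Col4a1 of the primitive endoderm list were higher and Cubn (−1.96) lower, while Gata6 (−0.52) did not pass. Foxf1 (1.38) of the mesoderm list was higher, and Hoxb1 (31 reads against 1), Mixl1 (−1.33) and Bmp4 were lower. H19 (2.29) and Plagl1 (1.20) of the imprinted list were higher, and Phlda2 (−1.94) and Peg10 (−1.17) lower. Mael (−1.32) and Sycp3 (−1.23) of the germline list were lower. Single lists also gave Rhox9 (1.42), Ier3 (1.32), the histone genes H1f2 (1.64) and H2bc4, the glycolysis genes Hk1 (1.06) and Eno2 (1.02), the stress gene Atf3 and the housekeeping gene B2m (1.37) as higher, and Gbx2 of the neuroectoderm and LIF lists as lower.

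The second comparison asked what the inhibitor did in Erk KO cells, 96 hours after Dox withdrawal. Of the 30 MAPK targets 4 were lower in the treated library. Spry4 was 48.4-fold lower (22.0 to 133), with 294 reads untreated and 6 treated, Etv4 was 4.66-fold lower (2.89 to 7.85), Dusp6 3.21-fold lower (2.61 to 3.98) and Myc 3.06-fold lower (2.46 to 3.84). The fibroblast markers were higher by about as much as in KH2 cells, whereas no naive pluripotency gene passed. Of 11920 genes tested, 160 were higher and 70 lower, which is 1.93%.

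Among the MAPK targets these 4 genes were lower in treated Erk KO cells, Fosb was higher and 25 did not pass, with a median of −0.31 against −0.09 to 0.11 for random lists. Egr1 (0.59), Fos (0.75), Spry2 (−0.46) and Etv5 (0.11) were among those not passing. No naive or general pluripotency gene passed. The medians were 0.16 and −0.25, outside the random ranges of −0.10 to 0.07 and −0.10 to 0.06, with Nanog at 0.38, Klf4 at 0.30, Pou5f1 at −0.06 and Sox2 at 0.04. Of 20 formative and primed genes 3 were lower, including Pou3f1 (−1.42) and Dnmt3a (−1.12), and 0 higher, with a median of −0.30, while Dnmt3b (−0.78) and Dnmt3l (−0.57) did not pass. Trh was 9.99-fold lower, and the matrix metalloproteinase genes Mmp10 (9.63-fold lower) and Mmp3 (8.89-fold lower), Porcn (8.06-fold lower), Serpinb2 (7.27-fold lower), Il1rl1 (5.93-fold lower) and Enox1 (5.42-fold lower) had the other lowest ratios. Bmp4 (5.65-fold lower) and Gbx2 (3.68-fold lower) also passed. In the fibroblast list 17 of 26 genes were higher and 0 lower, with a median of 1.61 against −0.09 to 0.09. Prelp was 54.2-fold higher and Col1a1 8.41-fold, at 25.9 RPKM untreated and 218 RPKM treated. Timp3 (2.86), Ptx3 (3.04), Ccdc80 (3.43), Aspn (3.33), Ly6a (2.96) and Prss23 (2.90) were also higher, and Ccn5 had 105 reads against 3. Of the cytoskeleton list 5 of 30 genes were higher (Acta2 at 2.60, Tagln at 1.58, Ccn2 at 1.51, Anxa3 and Myl9) and 0 lower. H19 (2.13) and Igf2 (1.44) were higher and Peg10 (−1.19) and Nnat lower among imprinted genes. The list of CDK inhibitors had no gene past the limit and a median of 0.19, with Cdkn1a at 0.78. The lists for p53 targets, both cell cycle phases, telomeres, repair, apoptosis, glycolysis, stress and the germline had none either, and Ccnd1 (−0.51), Tert (−0.27) and Gata6 (−0.25) were within 2-fold. Further genes that passed were Plat (1.22), Gsc and H1f2 (1.49), which were higher, and Nefm, which was lower.

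Across the 11668 genes compared in both pairs, the log2 ratios with PD0325901 had a Pearson r of 0.684 and a Spearman rho of 0.529, where genes are not independent replicates. The matrix gene Prelp was among 133 genes higher in both, where independent lists would share 5.30, and Spry4 among 35 genes lower in both, where they would share 0.53. No gene passed in opposite directions. The difference between the pairs reached 4-fold for 10 genes, 6 with a higher log2 ratio in KH2 cells (Acta1, Rtl8a, Birc7, Ogn, Pgpep1l and Alkal1) and 4 with a lower one (Ccl5, Spink1, Pdyn and Rims4). Most had few reads, but Acta1 had 30 and 158 reads in KH2 cells and 12 and 14 in Erk KO cells. An edgeR test of the difference over all 6 libraries, added after the data were seen, called 0 of 15103 genes in either direction, with 129 at an unadjusted p under 0.05. In that fit the sign of Spink1, with 1 and 0 reads in the Erk KO pair, turned from −2.78 to 1.19. No other tool was run on it.

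**Figure D2:**
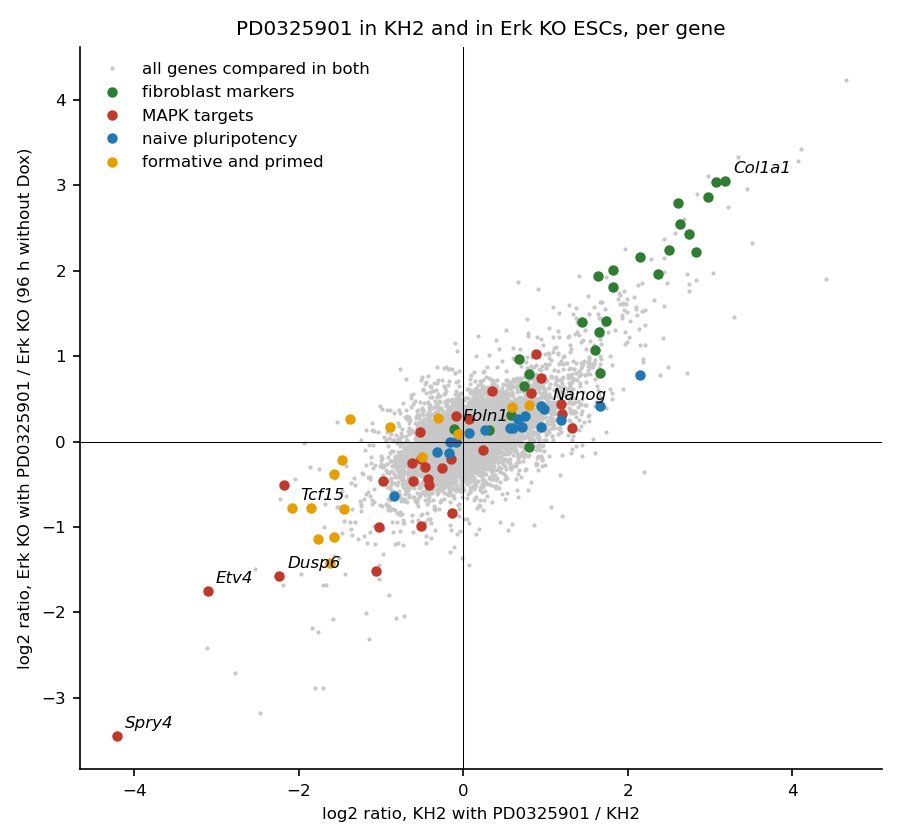
Log2 ratio of treated to untreated RPKM plus 0.5 for each gene in KH2 cells (horizontal axis) and in Erk KO cells (vertical axis), with 1 point per gene for the 11668 genes compared in both pairs (grey) and for 4 gene lists (green, fibroblast; red, MAPK; blue, naive; orange, formative). Spry4 lay at −4.21 and −3.45, and Col1a1 at 3.18 and 3.05.

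An effect of PD0325901 shared by both cell states was tested over the 4 libraries, with cell state as a block. The test, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, called 894 genes higher and 432 lower of 14782. The fit estimates 1 effect over both pairs, so a call does not require a change in each pair. This test has 1 residual degree of freedom per gene, from how far the 2 pairs differ. With a median of 13.8 prior degrees of freedom, the spread used was mostly borrowed across genes, and small p-values rest on that. By this test 3327 genes had an unadjusted p under 0.05. DESeq2 called 338 higher and 103 lower, and edgeR without the block called 0 in each direction, with 270 genes at an unadjusted p under 0.05. Spry4 had a log2 fold change of −4.84 (SE 0.193, adjusted p 2.24e-10 by edgeR) and Col1a1 of 3.13 (SE 0.0935, adjusted p 3.33e-11), each in the same direction in both pairs. Prelp was at 5.12, Ogn at 5.80, Aspn at 5.61, Ccn5 at 4.67, Ccdc80 at 4.29 and Adamts5 at 4.25. Hoxb1 (−4.66), Tfpi2 (−4.29), Spink1 (−3.89), Soga3 (−3.78), the macrophage metalloelastase gene Mmp12 (−3.74) and Tgm3 (−3.64) were among the genes with the lowest fold changes. Of these, Spink1 had 48 and 3 reads in untreated and treated KH2 cells but only 1 and 0 in Erk KO cells.

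In that test 12 of 30 MAPK targets were lower and 6 higher, or 15 and 7 adjusted over the list alone. Etv4 was at −2.97, Dusp6 at −2.03, Myc at −1.34, Spry2 at −0.73 and Ccnd1 at −0.47, whereas Fosb, Fos (0.89) and Egr1 (0.47) were higher. Of 18 naive genes 9 were higher and 1, Nr0b1 (−0.76), lower, or 11 and 1 adjusted over the list alone. Nanog had a log2 fold change of 0.68 (SE 0.124, adjusted p 0.00246 by edgeR), and Spic (1.27), Prdm14 (0.97), Tbx3 (0.72), Tfcp2l1 (0.68), Klf4 (0.53) and Dppa3 (0.53) also passed. Klf2 (0.36) and Esrrb (0.20) did not. Of 18 general pluripotency genes 9 were lower, including Utf1 (−1.22), Dnmt3l (−0.63) and Lin28a (−0.67), and 1, Fgf4, higher, or 11 and 2 adjusted over the list alone. Pou5f1 (−0.29) and Sox2 (0.04) did not pass. The formative list had 9 of 20 genes lower, among them Fgf5 (−1.99), Tcf15 (−1.68), Dnmt3a (−1.40), Dnmt3b (−1.33) and Lef1 (−1.02), and 1, Cdh2, higher, or 10 and 2 adjusted over the list alone. In the CDK inhibitor list Cdkn1a (1.14), Cdkn2b (1.10) and Cdkn1b (0.50) were higher and 0 lower, also when adjusted over the list alone. Of 30 p53 targets 7 were higher and 1 lower, or 9 and 3 adjusted over the list alone. Ccnd2 (0.90) was the 1 higher gene of 34 in the G1/S list and Ccnd1, Ccne1, Cdk6 and E2f2 were its 4 lower genes, with the same counts adjusted over the list alone. The fibroblast list had 20 of 26 genes higher and 0 lower, or 22 adjusted over the list alone. Timp3 was at 2.97, Lox at 2.72 and Thbs1 at 1.82, whereas Dcn (0.46) and Fbln1 (0.01) did not pass. The cytoskeleton list had 23 of 30 genes higher, with Acta2 at 2.68, and 0 lower, or 25 adjusted over the list alone. Imprinted genes went both ways, 6 higher and 4 lower, with H19 at 2.31 and Igf2 at 1.13, or 7 and 6 adjusted over the list alone. Bmp4 (−1.79), Gbx2 (−2.45) and Peg10 (−1.20) were lower and B2m (1.15) higher. The telomere list had 1 lower gene, Rtel1, and 0 adjusted over the list alone, and Tert was at −0.15. For G2/M, repair and ribosomal protein genes, both edgeR and DESeq2 called 0 in either direction, and edgeR called 0 when adjusted over the list alone.

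These list counts depended on the tool and the libraries. DESeq2 called 4 naive genes higher and 1 lower, 6 formative genes lower and 0 higher, 6 MAPK targets lower and 4 higher, 20 cytoskeleton genes higher and 19 fibroblast markers higher. It called 5 general pluripotency genes lower and 0 higher, 2 p53 targets higher and 1 lower, 1 CDK inhibitor higher, 1 G1/S gene higher and 1 lower, and 3 imprinted genes higher and 1 lower. With all 6 libraries in 3 states, edgeR called 103 genes higher and 15 lower. It then called 0 naive, 0 formative and 0 general pluripotency genes in either direction, 1 MAPK target lower and 0 higher, and 1 cytoskeleton gene, 1 p53 target, 1 CDK inhibitor and 1 G1/S gene higher. Imprinted genes had 1 higher and 1 lower, and 17 fibroblast markers were higher. That fit treats the 48 and 96 hour libraries without Dox as replicates.

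**Figure D3:**
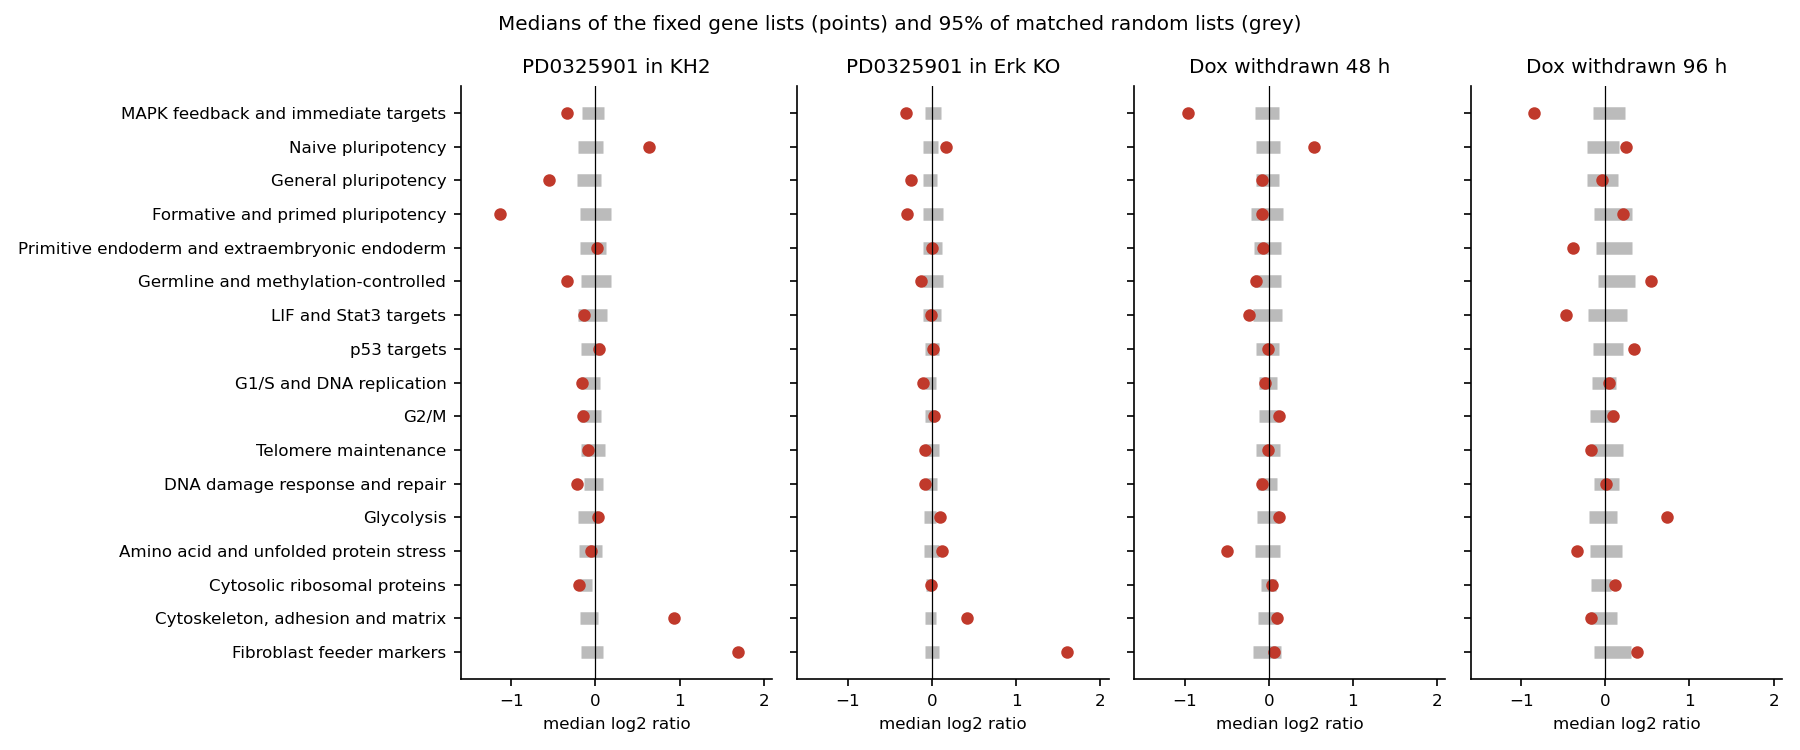
Median log2 ratio of 17 gene lists (red points) in 4 comparisons, with the middle 95% of 10000 expression-matched random lists (grey bars) on a shared horizontal axis. The fibroblast list lay at 1.70 and 1.61 in the PD0325901 pairs and at 0.07 and 0.38 in the Dox comparisons, and the MAPK list lay left of its random range in all 4.

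The third comparison, named in the design as Erk knockout, asked what differed when Dox was withdrawn for 48 hours. More MAPK targets passed as lower, 15, than with PD0325901 in either pair. Egr1, an immediate early transcription factor gene, was 21.6-fold lower (16.8 to 28.3), at 45.7 RPKM with Dox and 2.11 RPKM without, Spry4 was 15.5-fold lower (12.1 to 20.1) and Dusp6 8.31-fold lower (7.10 to 9.77). Of 18 naive pluripotency genes 6 were higher, with Spic 18.2-fold, Dppa3 10.9-fold and Nanog 3.78-fold higher (3.56 to 4.01), the last at 105 RPKM with Dox and 398 RPKM without. The fibroblast markers, in contrast to the PD0325901 pairs, had a median of 0.07, within the random range of −0.19 to 0.14. Of 11386 genes tested, 315 were higher and 242 lower, which is 4.89%.

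Of the 30 MAPK targets 15 were lower after 48 hours, 1 (Rasgef1a) was higher and 14 did not pass, with a median of −0.96 against −0.16 to 0.12. Etv4 (6.84-fold lower), Myc (5.45-fold lower), Fos (3.57-fold lower) and Spry2 (2.26-fold lower) were among the lower genes, and Etv5 (0.50) did not pass. In the naive list 0 genes were lower, and the median was 0.54. The higher genes included Prdm14 (1.93), Fbxo15 and Tcl1, whereas Klf2 (0.66), Zfp42 (0.54), Esrrb (−0.05) and Klf4 (−0.25) did not pass. Among general pluripotency genes Utf1 (−1.56) and Dnmt3l (−1.26) were lower and Fgf4 (1.27) higher, while Pou5f1 (0.18) and Sox2 (0.23) did not pass. The formative list split, with 4 genes lower, including Tcf15 (4.80-fold lower), Dnmt3a (3.54-fold lower) and Cdh2, and Otx2 higher, and Dnmt3b was at −0.80. Other genes with the highest ratios were the chemokine gene Cxcl1 (24.9-fold), the imprinted deiodinase gene Dio3 (35.1-fold), Pramel7 (log2 ratio 3.90), Cd84 (3.36), Bhmt (3.13) and Pramel6 (3.01). Pramel genes belong to a family with similar copies, so their counts are uncertain. Among the lowest were Nt5e (10.9-fold lower), Bmp4 (9.60-fold lower), Soga3 (7.69-fold lower), Gbx2 (6.57-fold lower) and Gadd45a (5.66-fold lower).

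Signalling and stress genes also differed at 48 hours. The Nodal targets Lefty1 (1.81) and Lefty2 (1.60) were higher and the BMP target Id1 (−1.41) lower among 17 genes. Of the amino acid and unfolded protein stress list 3 of 22 genes were lower and 0 higher, namely Chac1 (5.47-fold lower), Ddit3 (3.27-fold lower) and Trib3 (2.37-fold lower), with a median of −0.49 against −0.16 to 0.13. Gata6, a primitive endoderm factor gene, was 3.22-fold lower, the 1 passing gene of 26 in its list. Imprinted genes had 1 higher (Plagl1) and 5 lower, among them Grb10 (2.57-fold lower) and Meg3 (2.62-fold lower). Wnt targets had 2 higher (Apcdd1 and Dkk1) and 3 lower (Myc, Fzd7 and Cdx1) of 18. Cdk6 (2.61-fold lower) and E2f2 (2.40-fold lower) passed in the G1/S list, while CDK inhibitors, with Cdkn1a at 0.47, G2/M, telomere, repair, apoptosis and ribosomal protein genes had none passing. Further passing genes were Bnip3 (1.10), Gata3 (1.32), Rpl10l (1.83) and Dazl (1.04), which were higher, and Pdk1 (−1.75), Ddx4 (−1.06) and Gdf15, which were lower. Ccnd1 (−0.14), Tert (−0.37) and Map2k1 (0.64) were within 2-fold.

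Mek inhibition in KH2 cells and Dox withdrawal for 48 hours share no library. Their log2 ratios had an r of 0.395 across 11240 genes, 47 genes were higher in both where independent lists would share 7.45, and 50 were lower in both against 2.27, while 5 passed in opposite directions. In all 3 comparisons of the design 25 genes passed in the same direction. The 23 lower genes included Spry4, Dusp6, Etv4, Myc, Bmp4, Gbx2, Dnmt3a, Trh, Peg10 and Gadd45a, and the 2 higher genes were Saa3 and Ly6a.

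At 96 hours without Dox, compared with the same Dox-maintained library, the genes with the highest ratios included genes of the interferon response, a group noted after the values were seen. Isg15, a ubiquitin-like protein gene, had 0 reads with Dox and 175 reads at 96 hours, at least 55.1-fold higher against a floor of 3 reads in the Dox library, and Rtp4 had 0 and 283 reads, at least 89.2-fold higher. Usp18 had 1 and 372 reads, Irf7 had 3 and 225 reads, and Oasl2 was 106-fold, Irgm1 41.5-fold and Ifi27 40.5-fold higher. Nanog was 2.82-fold higher, and Bnip3 7.86-fold higher. Egr1 was 5.76-fold lower (5.02 to 6.63), Dusp6 3.91-fold lower (3.49 to 4.38) and Spry4 3.73-fold lower (3.27 to 4.26). Of 11804 genes tested, 899 were higher and 244 lower, which is 9.68%. TMM scaling moved the median log2 ratio by −0.11 and gave 768 higher and 318 lower, so the higher share went from 78.7% to 70.7%, and DESeq2 size factors moved it by −0.13 and gave 746 and 345, a higher share of 68.4%.

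Of the MAPK targets 13 were lower at 96 hours and 2 (Rasgef1a and Ier3) higher, with a median of −0.85 against −0.14 to 0.24, and Fosb (4.65-fold lower), Fos (3.95-fold lower) and Myc (2.25-fold lower) were among them. Etv4 (−0.86), Spry2 (−0.82) and Etv5 (0.75) did not pass. Of 18 naive genes 5 were higher, with Dppa3 at 3.04, Spic at 2.45 and Prdm14 at 1.84, and 3 (Tdh, Klf5 and Nr0b1) were lower, while Klf4 (−0.68) and Esrrb (−0.65) did not pass. Utf1 (−1.03) and Lin28a (−1.02) were lower and Pou5f1 was at 0.11. In the formative list Otx2 (2.05), Lef1 (1.87), Pou3f1 and Zic2 were higher and Tcf15 (−1.71) and Sox11 lower, with Dnmt3b at −0.48 and Dnmt3l, of the general list, at 0.74. Of 26 primitive endoderm genes 8 were lower and 0 higher, with a median of −0.39 against −0.11 to 0.32. They included Cubn (11.6-fold lower), Gata6 (6.96-fold lower), the endocytic adaptor gene Dab2 (4.66-fold lower) and Pdgfra (2.66-fold lower). Of 24 germline genes 7 were higher and 1 (Ddx4) lower, led by Dazl (2.18), Rpl10l (2.12) and Hormad1 (1.95). The glycolysis list had 8 of 23 genes higher and 0 lower, with Slc16a3 at 2.20, Egln3 at 2.07 and a median of 0.74 against −0.20 to 0.14.

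Of the LIF and Stat3 targets Bcl3 (−1.46), Junb (−1.28), Gbx2 (−2.07) and Klf5 were lower and Ier3 higher, with a median of −0.47 against −0.21 to 0.26. Among Nodal and BMP targets 3 were higher, including Lefty2 (7.35-fold higher) and Id4, and Id1 (−1.43) was lower. Imprinted genes had 3 higher, led by Mest, and 7 lower, led by Grb10 (4.53-fold lower). Trophoblast genes had 6 higher, including Ascl2 (1.85) and Esx1 (1.70), and 2 lower (Krt8 and Peg10). Trib3 (−1.33), Chac1 (−1.29) and Atf4 (−1.05) of the stress list were lower and 0 higher. Trp73, Btg2 and Trp53inp1 were the 3 higher of 30 p53 targets, and Cdkn1a (0.88) did not pass. The 2-cell-like list had 2 higher genes (Zscan4f and Gm5662) on 3 genes tested. The fibroblast list had Igfbp4 (2.54), Dcn (1.89) and Lox higher and Mgp (−1.63) lower, with a median of 0.38 against −0.13 to 0.31 for random lists, and the cytoskeleton list had Anxa2 higher and Acta2 lower. In the neuroectoderm list Nes (1.35) was higher and 4 genes, Gbx2, Pax6 (−1.92), Sox1 and Neurod1, were lower. The housekeeping genes B2m (1.69) and Tfrc (1.55) were higher, as were Bok, Kif23 and Cbx8, each the 1 passing gene of its list. No telomere, repair, G1/S, CDK inhibitor, cholesterol, ribosomal protein or histone gene passed, and Tert (0.05) and Ccnd1 (−0.21) were within 2-fold. Of 21 histone genes only 3 reached the limits on reads and RPKM, so the others could not pass. Pramel7 (48.8-fold) was also among the 8 highest, and Gna14 (10.4-fold lower), Car4 (5.62-fold lower) and Cacng7 (5.11-fold lower) among the 8 lowest.

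Egr1 and Spic were among the genes that passed in the same direction at both times without Dox, 245 higher and 113 lower, where independent lists would share 18.3 and 5.21. The r of 0.723 across genes compares with 0.533 for simulated groups without a difference, and the covariance of 0.209 with 0.0135, so part of the excess may come from the shared Dox library and could not be split off. The 96 hour ratios and those of PD0325901 in Erk KO cells share the untreated 96 hour library, which pulls them apart. Their r was 0.077 against −0.513 simulated, their covariance 0.0153 against −0.0128, 13 genes were higher in both against 8.13 for independent lists, 17 lower against 1.10 and 19 passed in opposite directions. PD0325901 in KH2 cells and 96 hours without Dox had an r of 0.303, with 81 genes higher in both against 23.2 for independent lists, 37 lower against 2.34 and 16 opposite. PD0325901 in Erk KO cells and 48 hours without Dox had an r of 0.292, with 5 genes higher in both, 30 lower and 6 opposite.

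The engineered line with Dox was also compared with untreated KH2 cells. These libraries differ in both line and Dox, whose effects cannot be told apart. Pygl (40.9-fold lower), Adm (37.5-fold lower), Plac8 (35.5-fold lower), Ndufa4l2 (33.7-fold lower), Ndrg1 (16.4-fold lower) and Ddit4 (16.4-fold lower) were among the lowest, and H2-Ab1 had 1 read against 108. The Y-linked genes Eif2s3y (22.8-fold lower), Ddx3y, Uty and Uba1y were lower. Of 12421 genes tested, 343 were higher and 2662 lower, which is 24.2%. This split moved with the scaling, to 1006 higher and 1419 lower with TMM, which shifted the median log2 ratio by 0.39, and to 1141 and 1325 with DESeq2 size factors, which shifted it by 0.44. The log2 ratio decreased with transcript GC content (Spearman −0.359), from a median of −0.01 below the 20th percentile of GC to −0.79 above the 80th, and after a GC correction 611 genes were higher and 1348 lower.

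Among glycolysis genes 16 of 23 were lower and 0 higher in the Dox-maintained line, with a median of −1.33, including Bnip3 (9.02-fold lower), Egln3 (8.73-fold lower) and Pgk1 (3.90-fold lower). The fibroblast list had 14 of 26 genes lower, with Lox 9.74-fold, Fbln1 6.60-fold and Col1a1 5.62-fold lower, and 0 higher. Of 30 p53 targets 15 were lower, among them Cdkn1a (2.60-fold lower). The primitive streak gene T (17.3-fold lower), the Nodal inhibitor gene Lefty1 (10.8-fold lower), Fgf15 (12.2-fold lower) and Fgf8, at least 13.1-fold lower against a floor of 3 reads in the Dox library, were lower. MAPK targets went both ways, with Etv4 (6.52-fold lower), Egr1 (3.67-fold lower) and Fos (2.35-fold lower) among 10 lower and Epha4 and Etv1 higher, while Dusp6 (0.62) and Spry4 (−0.39) did not pass. The pluripotency genes Nanog (−0.21), Pou5f1 (−0.47), Sox2 (0.31) and Zfp42 (0.55) did not pass. Of 18 naive genes Fbxo15, Tfcp2l1 and Klf5 were higher and Dppa3 and Tcl1 lower, with a median of 0.48 against −0.46 to 0.31. Of 18 general pluripotency genes Dppa4 and L1td1 were higher and Dppa5a and Utf1 lower. These ratios also depend on the scaling, since TMM shifted the median log2 ratio over genes by 0.39. Dppa4 (2.86-fold higher), L1td1 (2.49-fold), Fbxo15 (2.25-fold), the neural gene Sox1 (10.2-fold), Nlrp4f (7.75-fold), Eya1 (6.76-fold) and Mras (6.38-fold) were higher, and Dppa3 was 4.51-fold lower. Map2k1 was at −1.08.

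**Figure D4:**
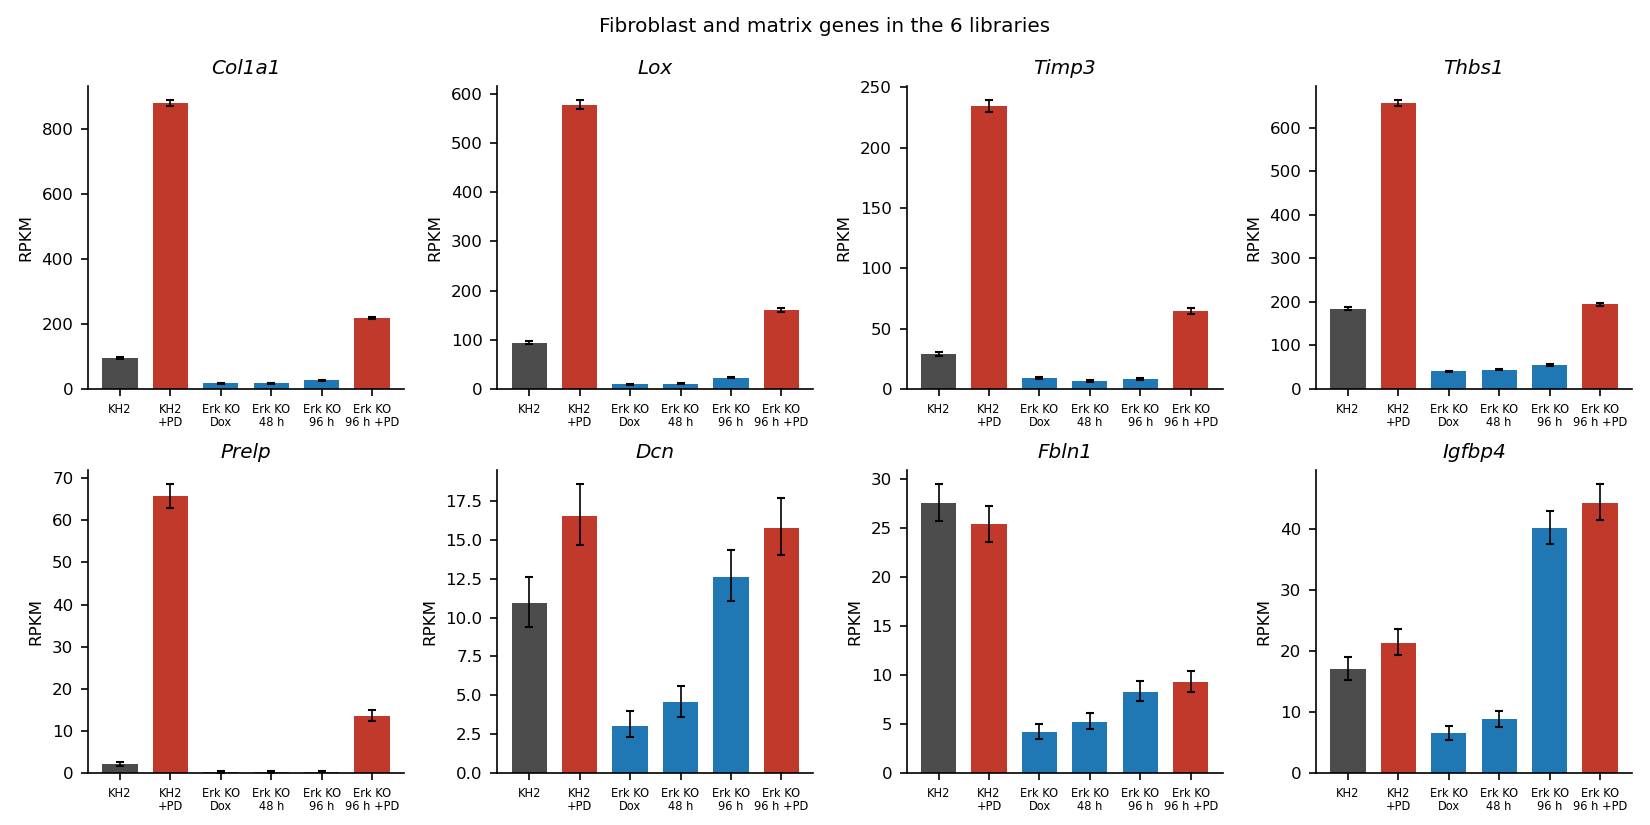
RPKM of 8 fibroblast and matrix genes in the 6 libraries, with 1 bar per library. Error bars are exact 95% Poisson counting intervals. Untreated KH2 is grey, PD0325901 red and the engineered line without inhibitor blue. Prelp, which is shown, is not in the fixed list of fibroblast markers. Col1a1 was at 878 and 218 RPKM in the treated libraries and at 96.4 and 25.9 RPKM in their untreated partners, and Fbln1 did not differ by 2-fold within either pair.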

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

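All tests in this part were chosen after the result was seen. Genes that went opposite ways under the same treatment, each ratio with a counting interval that excluded 1, are given first. Birc7, an apoptosis inhibitor gene, had a log2 ratio of 1.20 with PD0325901 in KH2 cells and −0.87 in Erk KO cells, on 4, 16, 27 and 12 reads. The edgeR test over all 6 libraries did not call its difference (p 0.138), but the spread of that test includes the difference between 48 and 96 hours without Dox. The other 4 genes, whose differences were not tested, went opposite ways at 48 and 96 hours without Dox, both measured against the same Dox-maintained library. The smooth muscle actin gene Acta2 was at 0.16 and −1.21, the Wnt pathway factor gene Lef1 at −0.51 and 1.87, Dnmt3l at −1.26 and 0.74, and the hypoxia-induced hydroxylase gene Egln3 at −0.32 and 2.07.

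Fibroblast markers were higher with PD0325901 in both cell states. In KH2 cells the 14 markers that were lower in the Dox-maintained line had a median ratio of 4.42, with quartiles of 1.76 and 6.82, Fbln1 at 0.92 and Col1a1 at 9.11. Xist, scarce in male ESCs, had a ratio of 2.38 (2.11 to 2.69), below that median but within the quartiles, so it does not decide on a larger fibroblast share. Such a share alone, of unchanged fibroblasts, would raise markers read only from fibroblasts by 1 common factor. The ratios were spread, but reads that the ESCs add to a marker would bring its ratio nearer to 1. These reads could not be separated, so the spread does not decide. A larger share stays open as part or the whole of the change. A response of the ESCs to lower Erk activity would show without Dox as well, where the list's median was 0.068 at 48 hours (−0.16 to 0.16 over members), below the 0.80 set as its lower bound. At 96 hours the median was 0.38 (0.14 to 0.58), above its random range of −0.13 to 0.31 but below the same bound, so a smaller response stays open. In Erk KO cells the summed Y-linked reads, scarce in this line, do not decide on a larger fibroblast share either. Their ratio of treated to untreated cells was 1.82 (1.32 to 2.51). This interval lies below the markers' median ratio of 3.76 but overlaps their quartiles, 1.73 to 6.77. The spread of the markers' ratios departs from 1 common factor here too, with the same limit. A response of feeder-type fibroblasts to the inhibitor may account for the matrix genes and stays open, since no library held such cells alone and the labels do not state whether feeders were used.

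Of 30 MAPK targets 4 were lower with PD0325901 in cells that had been without Dox for 96 hours. Fibroblast reads as the whole source of the remaining target reads cannot be told apart from other sources. From 48 to 96 hours the 6 targets that were lower with PD0325901 in KH2 cells had a median log2 ratio of 1.12 (0.42 to 1.63 over members), above the fibroblast quartiles of 0.13 and 0.77, but the interval overlaps them. The whole MAPK list had a median of 0.12 and the fibroblast markers of 0.34. The total of remaining Mapk3 reads was not lower in the treated library, at a ratio of 1.36 (1.07 to 1.74). Fibroblast reads may have added to that total, since the summed Y-linked reads had a ratio of 1.82 (1.32 to 2.51). Less Mapk3 transcript within the ESCs therefore stays open. Action of the inhibitor on Mek-dependent signalling that remained after Dox withdrawal may account for the lower targets, and so may an effect of the compound apart from Erk. Neither was tested, since no library measured protein or kinase activity.

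Interferon-stimulated genes were higher at 96 hours without Dox, with a median log2 ratio of 3.39 (1.93 to 3.93 over 26 members). These members were chosen after their rise was seen, so the range does not test the rise itself. The fibroblast markers, a list fixed beforehand, had quartiles of −0.04 and 0.67 in the same comparison, which argues against a larger share of otherwise unchanged fibroblasts as the whole cause. A change within fibroblasts stays open. The GC-corrected median was 3.31 (1.89 to 3.91), so a GC trend between the libraries did not account for it. Lower Erk activity alone cannot be told apart from other differences of these libraries, since the median with PD0325901 in KH2 cells was 0.24 (0.08 to 0.51) and that at 48 hours without Dox 0.83, with a lower bound of 0.41. Time without Dox, passage and an infection or other stimulus of a single culture stay open as untested explanations, with 1 library per time point.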

How the results depend on the processing

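The GC-corrected ratio, the count without the fibroblast and cytoskeleton lists and the test of the difference between the pairs were chosen after the data were seen. The difference between the pairs reversed for Spink1, to 1.19 in the 6-library test from −2.78, and no other called result reversed under the alternatives run. Some list medians near 0, such as that of the G2/M list at 96 hours without Dox, changed sign with TMM scaling. Of the values that answer a comparison, 98 stayed on their side of the limit or within 1.5 times the count, 28 were smaller, 7 larger and 5 correlations moved. For single genes 3607 calls were the same, 268 were lost and 10 gained, and of the list medians 398 were the same and 95 moved. A 3-fold limit, stricter by construction, gave 144 higher and 39 lower genes with PD0325901 in KH2 cells, 60 and 23 in Erk KO cells, 92 and 66 at 48 hours without Dox, 320 and 55 at 96 hours, and 51 and 893 for the Dox-maintained line against KH2. A pseudocount of 0.1 gave 275 lower genes in KH2 cells and 112 in Erk KO cells. With a pseudocount of 1 there were 44 lower genes in Erk KO cells and 160 at 48 hours without Dox, and 2 genes differed between the pairs in each direction. An RPKM of at least 3 left 39 lower genes in Erk KO cells and 3 with a higher ratio in KH2 cells than in Erk KO cells. It moved r to 0.728 between the PD0325901 pairs, 0.430 between PD0325901 in KH2 cells and 48 hours without Dox, 0.748 between 48 and 96 hours, 0.114 between 96 hours and PD0325901 in Erk KO cells, and 0.351 between PD0325901 in KH2 cells and 96 hours, on fewer genes with low counts. TMM scaling left 3 genes with a higher ratio in KH2 cells and gave 1006 higher and 1419 lower genes for the Dox-maintained line, DESeq2 size factors gave 1141 and 1325, and the GC-corrected ratio 611 and 1348. In the common test DESeq2 called 338 higher and 103 lower, no block 0 and 0, all 6 libraries with 3 states 103 and 15, no scaling 705 lower, and 6 libraries with 4 states 704 lower. Without the block the difference between cell states enters the spread, and with 3 states so does that between 48 and 96 hours. The edgeR test of the difference between the pairs over 6 libraries called 0 genes higher and 0 lower in KH2 cells, against 6 and 4 by size, and its spread includes the difference between 48 and 96 hours. For the scaling, pseudocount and DESeq2 counts the cause was not tested. Depth limits genes near the floor of 3 reads, such as Fgf5, Ogn and Hoxb1, for which the direction is better supported than the size.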

Other observations

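The gene groups in this part, and the 1 comparison of 96 with 48 hours without Dox, were chosen after their values were seen, and they are described without a test. Among 26 interferon-stimulated genes, 24 were higher at 96 hours without Dox and 0 lower, 8 were higher at 48 hours with a median log2 ratio of 0.83, 3 were higher and 0 lower with PD0325901 in KH2 cells, with a median of 0.24, and 0 passed with PD0325901 in Erk KO cells, where the median was 0.10. Isg15 was at 9.02 RPKM in untreated and 14.8 RPKM in treated KH2 cells, 0 with Dox, 3.54 RPKM at 48 hours, 23.2 RPKM at 96 hours and 29.1 RPKM at 96 hours with PD0325901. In the order untreated KH2, treated KH2, with Dox, 48 hours, 96 hours and 96 hours with PD0325901, Ifit1 had 20, 69, 3, 28, 236 and 297 reads. The engineered line with Dox had 10 of these genes lower than KH2 cells and 0 higher.

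Among 23 hypoxia-induced genes, 20 were lower in the Dox-maintained line than in KH2 cells and 0 higher, with a median of −2.34. At 96 hours without Dox 12 were higher than with Dox and 0 lower, with a median of 1.17, and at 48 hours 4 were higher and 1 lower. Between 48 and 96 hours 13 were higher and 0 lower. Ndrg1 had 1200 and 2244 reads in untreated and treated KH2 cells, 76 with Dox, 351 at 48 hours, 1429 at 96 hours and 1981 at 96 hours with PD0325901. Bnip3, a mitophagy receptor gene, had 4460, 5186, 512, 1142, 4258 and 4768 reads in the same order, and Ndufa4l2 had 553, 831, 17, 41, 351 and 389.

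From 48 to 96 hours without Dox 5 MAPK targets were higher (Dusp6, Spry4, Etv4, Egr1 and Myc) and 0 lower, while 3 naive genes were lower and 0 higher, with a median of −0.39. The interval of the Mapk3 ratio between these libraries held 1, at 0.98 (0.76 to 1.28). The metalloproteinase gene Mmp3 had 21 reads with Dox, 144 at 48 hours, 342 at 96 hours and 38 at 96 hours with PD0325901, and Mmp10 had 17, 112, 234 and 24.

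The summed Y-linked reads were 833 and 867 in the KH2 libraries and 49, 42, 63 and 113 in the engineered line, in the order with Dox, 48 hours, 96 hours and 96 hours with PD0325901. Xist, the RNA of the inactive X chromosome, had 391 and 927 reads in KH2 cells and 66, 74, 96 and 150 in the engineered line. Its ratio of treated to untreated cells was 2.38 in KH2 cells (2.11 to 2.69) and 1.58 in Erk KO cells (1.22 to 2.07).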
